A study of Mus musculus with 6 samples.

How the data were processed

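RNA was measured in 6 hemibrains of newborn mice at postnatal day 0, 3 labelled Celf2 -/- and 3 labelled Celf2 +/-. CELF2 is an RNA-binding protein. The control group carries 1 Celf2 allele, so the contrast is null against heterozygous and not against wild type. Replicates are named by the pup numbers in the labels, 2, 4 and 10 for the null group and 6, 7 and 11 for the heterozygous group. The numbers are not shared between groups, and the labels give no litter, sex or batch. The p-values therefore measure the spread between these samples.

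The authors deposited a table of whole-number read counts per gene symbol, with 24391 symbols and a length in bases for each. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a stranded total-RNA kit for low input, whereas the series' design text and the molecule field name poly(A) RNA. The conflict was not resolved here, and levels of RNA without a poly(A) tail depend on it. Per the submitters' processing notes, the tools named were CASAVA, cutadapt, STAR, Picard, bedtools and MACS2 and the builds mm9 and hg19, with no role or version. The counting tool, strand setting and annotation are not given in the sources used here, so overlapping, antisense and near-identical genes, such as histone and globin genes, are uncertain. No other sample's columns were in the table.

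Counts summed to between 28831997 and 36531980 per library. The smallest pairwise chi-square per gene was 11.2, so no pair of libraries agreed within sampling noise. Genes were kept by edgeR's filterByExpr with default settings, which left 15925. The test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with TMM factors, robust dispersion and Benjamini-Hochberg adjustment at 0.05. Standard errors are the fold change divided by the square root of the F statistic. Levels are CPM computed with TMM-scaled library sizes, given as mean ± SD. The biological coefficient of variation was 13.9%. Upper limits for a count of 0 are 3 counts of the library total and cover counting error only.

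The tests, 41 gene lists with 582 members, the alternatives and the rule for named genes were fixed before the data were examined. Of the members, 562 were found in the table by current or older symbol. Lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 40 lists with at least 2 tested members, and again with an estimated correlation. The list of mitochondrially encoded genes had no tested member. The fry test asked whether each list moved one way and, separately, whether its genes changed in either direction. The rule named Celf2, every gene that passed with a mean of at least 50 counts and no overlap between groups, the 5 genes with the smallest p in each direction with the same conditions, and up to 2 members of each list. Predicted-gene symbols were left out. Some genes that the rule names are not reported here. Genes named outside the rule are said to be chosen after their values were seen.

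Annotated 3′ UTRs of the mouse reference GRCm38 were searched for the 11-mer TGTTTGTTTGT, a GU-rich element of the kind CELF proteins bind. Of the tested genes, 93.5% had an annotated 3′ UTR. Because the reference differs from the build named in the notes, it served for names, sequence, GC content and gene order, and no coordinates are given. Genes with the element were compared with the other searched genes by camera and, in 10000 draws matched on 3′ UTR length and expression, by a two-sided permutation test. Tested genes among the 50 annotated protein-coding genes on each side of Celf2 on chromosome 2 formed another set. The permutation test of Celf2 was exact and two-sided over all splits of 3 against 3, for which the smallest possible p is 0.1.

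Alternatives were DESeq2 size factors, upper-quartile factors, library size alone, other low-count filters, the DESeq2 1.42.0 Wald test, limma-voom, dispersion without robust estimation, removal of sex-linked genes, a Y-linked covariate, an offset for GC content and length, and leaving out each library. The steps were tested on simulated counts for the null against heterozygous comparison. At 15793 genes run, 41 of 100 genes changed 1.5-fold and 73 of 100 genes changed 2-fold were recovered, with 6 false calls. A list raised 1.3-fold in every member was called, and it was the 1 list called. The simulated genes were drawn independently of each other, so false calls of lists with correlated genes were not tested. In the data the estimated inter-gene correlation was 0.35 for the hindbrain list and 0.97 for the immediate-early list.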

Results

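Gene expression was compared between hemibrains of newborn mice labelled Celf2 -/- (null, n = 3) and Celf2 +/- (heterozygous, n = 3). The comparison asked how transcript levels differ when the remaining Celf2 allele is also lost. Library totals were 28831997, 33104472 and 28972097 counts for null replicates 2, 4 and 10, and 36531980, 28854234 and 33587432 counts for heterozygous replicates 6, 7 and 11. The ribosomal RNA precursor Rn45s took 11.8% of the counts in null replicate 2 and between 0.194% and 1.27% in the other libraries. Xist, expressed from the inactive X chromosome, reached 1140 CPM in heterozygous replicate 7, 1350 CPM in null replicate 4 and 1270 CPM in null replicate 10. The Y-linked gene Ddx3y had 0 counts in these 3 libraries, which allows up to 0.104 CPM, and 65.5 to 80 CPM in the others. The highest correlation of log2 CPM between libraries, across genes, joined heterozygous replicate 11 and null replicate 10 (r = 0.9917).

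Celf2 itself was at 408 ± 48.5 CPM in heterozygous libraries and 390 ± 58.4 CPM in libraries labelled null (SD, n = 3 each; exact two-sided permutation p = 0.7). Single libraries held 459, 403 and 362 CPM in heterozygous replicates 6, 7 and 11, and 448, 390 and 331 CPM in null replicates 2, 4 and 10. The log2 fold change was -0.07 (SE 0.12, 95% interval -0.32 to 0.19, edgeR adjusted p = 0.955). The level in libraries labelled null was thus 95.6% of the heterozygous level, with an interval of 79.9% to 114%. Gene totals do not show which exons were read, so they neither check the genotype labels nor measure functional transcript, and every direction given here rests on the labels. The fold change was 0.03 without heterozygous replicate 6 and 0.04 without null replicate 10.

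Proz, which encodes the plasma protein Z of the coagulation system, fell from 4.70 ± 0.48 to 1.27 ± 0.23 CPM in libraries labelled null (log2 fold change -1.89, SE 0.22, edgeR adjusted p = 0.0492). Camk2a, a kinase subunit of excitatory synapses, was at 110 ± 9.12 CPM in heterozygous libraries and 66.0 ± 5.13 CPM in those labelled null (-0.74, SE 0.09, adjusted p = 0.0517). Nrgn, a postsynaptic calmodulin-binding protein, was at 119 ± 5.07 and 87.4 ± 1.91 CPM (-0.45, adjusted p = 0.213). Neurod6, a transcription factor of cortical excitatory neurons, was at 178 ± 8.82 and 258 ± 14 CPM (0.53, SE 0.07, adjusted p = 0.062). Each of these 4 genes separated the groups without overlap, which was a condition for naming them and adds nothing to their p-values. Camk2a passed with upper-quartile factors (adjusted p = 0.0293), library size alone (0.0132), no low-count filter (0.00418), the GC and length offset (0.0397), DESeq2 (3.18e-08) and pups 10 and 11 as a term (0.00785). Neurod6 passed with no low-count filter (0.0139), the offset (0.0397), DESeq2 (1.95e-06) and that term (0.00785), and Nrgn with DESeq2 (1.69e-04) and that term (0.0476). That term was chosen after the data were seen. Camk2a, Neurod6 and Nrgn passed in no other setting, nor in any fit that left out a library.

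Of 15925 genes tested, edgeR's quasi-likelihood test called 1 lower and 0 higher in libraries labelled null, and DESeq2 called 25 lower and 39 higher. At an unadjusted p of 0.05, edgeR counted 1124 genes against 796 by chance, 658 of them higher and 466 lower. Other splits of the 6 libraries, which mix the genotypes, gave up to 2089 such genes. Among them 3 (1512, 1788 and 2089) exceeded the genotype split. All 3 set heterozygous replicate 11 and null replicate 10, the pair with the highest correlation, on the same side. On the second principal component these lay at -24 and -18.6, and the other libraries between -0.8 and 23.6. The split of heterozygous replicates 6 and 11 and null replicate 10 against the others also joined that pair and counted 756. Without single libraries the count for the genotype comparison ranged from 599 to 1554. The 599, without heterozygous replicate 7, lay below the number expected by chance, and the 1554 came without heterozygous replicate 11. The count was 425 with the mean Hox level as a covariate. It was 1762 with pups 10 and 11 (null replicate 10 and heterozygous replicate 11) as a term. Both settings were chosen after the data were seen. The mean Hox level did not overlap between the genotypes, so as a covariate it also takes up genotype differences. The groups did not overlap for 2019 genes, or 12.7%, where chance gives 10%. The share of higher genes among the 1124 was 58.5%, against 47.3% with upper-quartile factors and 16.7% with library size alone. The median log2 fold change over all genes tested was -0.001, against -0.021 with upper-quartile factors and -0.086 with library size alone. List medians given below for library size alone carry that shift of all genes. The other genes with the smallest p above the threshold and higher values were Tenm4 (log2 fold change 0.48), the lipid synthesis enzyme Acly (0.58), Fosl2 (0.82) and Enc1 (0.39), each with an adjusted p of 0.213. Lower values were found for Phyhd1 (-0.90, adjusted p = 0.213) and Rasgrp2 (-0.46, adjusted p = 0.323). DESeq2 called all 6 of these genes, Acly (adjusted p = 3.51e-04) and Fosl2 (adjusted p = 5.74e-05) among them. The call of Proz was absent with limma-voom, with DESeq2 size factors and without any of heterozygous replicates 6, 7 and 11 and null replicates 2 and 4, where its fold change lay between -1.96 and -1.74. It was also absent with a CPM minimum, no robust dispersion, structural RNAs removed and the Hox covariate.

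**Figure D1:**
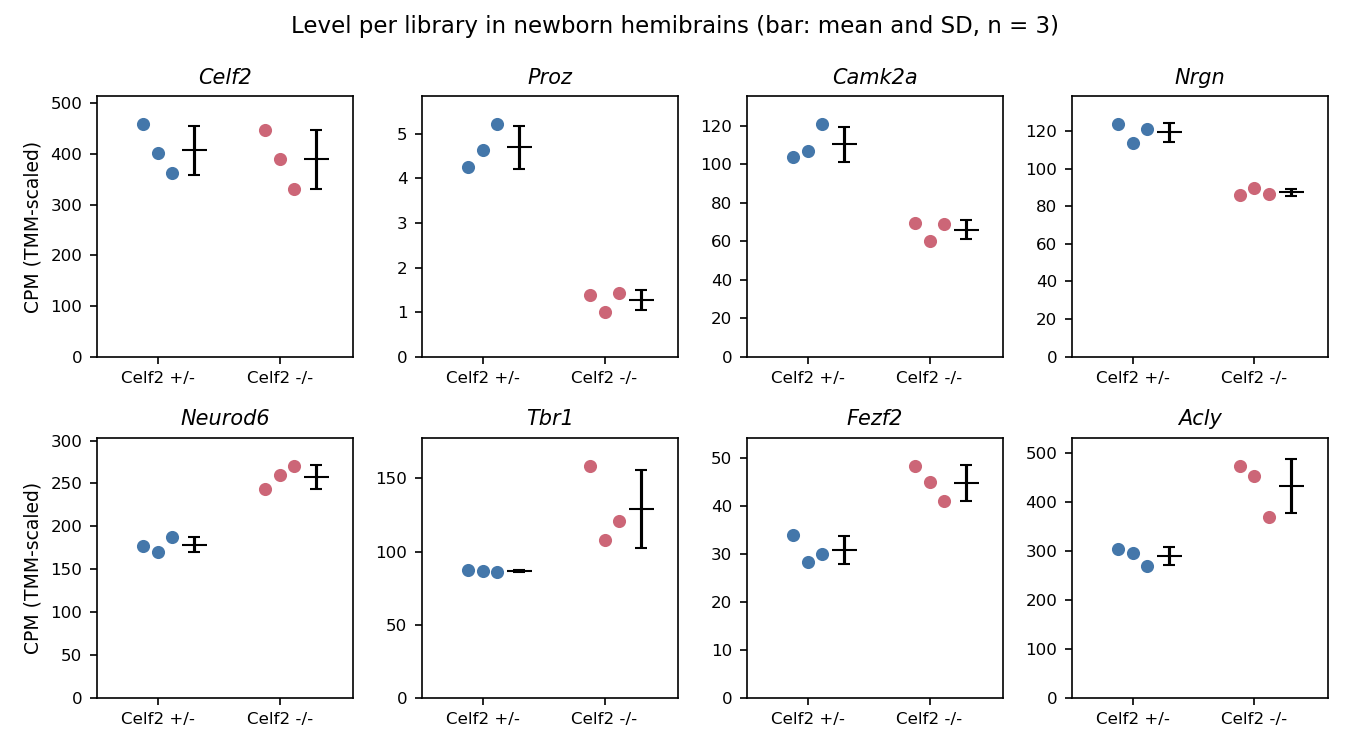
CPM of 8 genes in each of the 6 libraries, heterozygous in blue and labelled null in red, with mean and SD (n = 3) beside the points. Celf2 overlaps between the groups, at 408 and 390 CPM on average, while Proz, Camk2a, Nrgn, Neurod6, Tbr1, Fezf2 and Acly do not overlap. For Proz, Camk2a, Nrgn, Neurod6 and Acly the lack of overlap was a condition for naming them.

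Lists of telencephalic identity genes and of cortical neurons were called higher in libraries labelled null at the preset correlation, and the cortical lists had smaller medians. All 10 telencephalic identity genes had positive fold changes, with a median log2 fold change of 0.32 and a camera adjusted p of 8.71e-10 (adjusted p = 0.279 with an estimated correlation). Adjusted over the list alone, 6 of the 10 rose, Neurod6 and Neurod2 (0.33) among them. Among 16 deep-layer and subplate genes 10 were positive and 6 negative, and the median was 0.14 (adjusted p = 0.00104, and adjusted p = 0.319 with an estimated correlation). Adjusted over the list alone, 3 rose, including Fezf2 (0.54) and Tbr1 (0.57), transcription factors of corticofugal neurons. Among 13 upper-layer genes 11 were positive and 2 negative, and the median was 0.07 (adjusted p = 0.00627, and adjusted p = 0.325 with an estimated correlation), and 2 rose, adjusted over the list alone, Pou3f3 (0.34) among them. With library size alone, where the median over all genes tested was -0.086, the deep-layer median was 0.05 and the upper-layer median -0.03. With the mean Hox level as a covariate the telencephalic median was 0.20, and the upper-layer call was lost (adjusted p = 0.18) although its median was 0.10. The deep-layer median was 0.08 without null replicate 4, the upper-layer median lay between 0.03 (without null replicate 2) and 0.14 (without null replicate 10), and the upper-layer adjusted p was 0.0709 without heterozygous replicate 11. Over all genes tested, 0 members of these 3 lists passed.

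Axon guidance and adhesion genes had mostly positive fold changes. Of 29 members, 23 had positive fold changes (median 0.20, adjusted p = 3.44e-10, and adjusted p = 0.325 with an estimated correlation). Adjusted over the list alone, 5 rose and 0 fell, against 0 over all genes tested. They included Cntn2 (0.37), an adhesion protein of growing axons, and Nrp1 (0.47), a semaphorin receptor. The list deviated from its average by 0.13, 0.18 and -0.04 in null replicates 2, 4 and 10 and by -0.13, 0 and -0.13 in heterozygous replicates 6, 7 and 11, so null replicate 10 lay below heterozygous replicate 7. The list median was 0.12 with library size alone. Of 17 cholesterol synthesis genes, 16 were positive (median 0.19, adjusted p = 1.82e-05, and adjusted p = 0.325 with an estimated correlation), with Lss at 0.27 and Fdft1 at 0.27, and 0 passed by either adjustment. The Hox covariate ended this call (median 0.09, adjusted p = 0.273), and the median was 0.10 with library size alone and 0.12 without heterozygous replicate 7 or null replicate 2. Among 9 genes of intermediate progenitors and newborn neurons the median was 0.33 (adjusted p = 0.0145, and adjusted p = 0.488 with an estimated correlation), with 0 members passing by either adjustment, Eomes at 0.60 and Rnd2 at -0.29. That adjusted p was 0.464, with a median of 0.19, without heterozygous replicate 11 and 0.127 without null replicate 2.

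Hindbrain and cerebellum genes were lower in libraries labelled null, with 12 of 13 members negative and a median log2 fold change of -1.91 (adjusted p = 1.65e-12, and adjusted p = 0.325 with an estimated correlation). Adjusted over the list alone, 6 fell and 0 rose, against 0 over all genes tested. Hoxb2 fell, adjusted over the list alone, from 2.88 ± 2.43 to 0.367 ± 0.152 CPM (-2.93). The mean log2 CPM of 8 Hox genes, which mark tissue from the hindbrain backwards, was 0.98, 3.71 and -0.08 in heterozygous replicates 6, 7 and 11 and -1.57, -0.44 and -1.34 in null replicates 2, 4 and 10. Midbrain genes had a median of -0.31 (adjusted p = 0.0897). Chosen after their values were seen, the midbrain genes En1 and Slc6a3 were at 0.630 and 1.10 CPM in null replicate 2, with En1 at 6.81 to 11.0 CPM and Slc6a3 at 6.83 to 10.4 CPM in the other libraries. The hindbrain median was -0.45 with the Hox covariate, -1.29 without heterozygous replicate 7 and -1.59 without null replicate 2.

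Markers of astrocytes, of the oligodendrocyte lineage and of the striatum were also lower. All 10 astrocyte genes were negative (median -0.27, adjusted p = 1.82e-06, and adjusted p = 0.325 with an estimated correlation), and Apoe (-0.39) fell, adjusted over the list alone. S100b was at -0.69. Of 11 oligodendrocyte lineage genes 10 were negative (median -0.12, adjusted p = 0.0173, and adjusted p = 0.325 with an estimated correlation), and the myelin gene Mag (-0.90) fell, adjusted over the list alone. Of 10 striatal genes 9 were negative (median -0.09, adjusted p = 0.0145, and adjusted p = 0.325 with an estimated correlation), and the enkephalin precursor Penk (-0.68) fell, adjusted over the list alone. Over all genes tested, 0 members of these 3 lists passed. Without null replicate 10 the adjusted p was 0.232 for the oligodendrocyte list and 0.232 for the striatal list, which also reached 0.0697 without heterozygous replicate 11 and 0.112 with the Y-linked covariate. The Hox covariate ended the astrocyte call (median -0.15, adjusted p = 0.0685) and the oligodendrocyte call (median -0.05, adjusted p = 0.289). The striatal median moved the other way, to -0.15. The mean Hox level separates the genotypes, so these shifts do not assign a cause. Without single libraries the striatal median lay between -0.18 (without null replicate 2) and -0.02 (without null replicate 10), and the oligodendrocyte median was -0.19 without null replicate 4. With library size alone these medians were -0.19 and -0.20. In the same libraries the hindbrain list deviated from its average by 0.72, 1.57 and 0.22 in heterozygous replicates 6, 7 and 11 and by -1.23, -0.32 and -0.55 in null replicates 2, 4 and 10, and the astrocyte list by 0.05, 0.28 and 0.16 and by -0.40, 0.04 and -0.14.

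**Figure D2:**
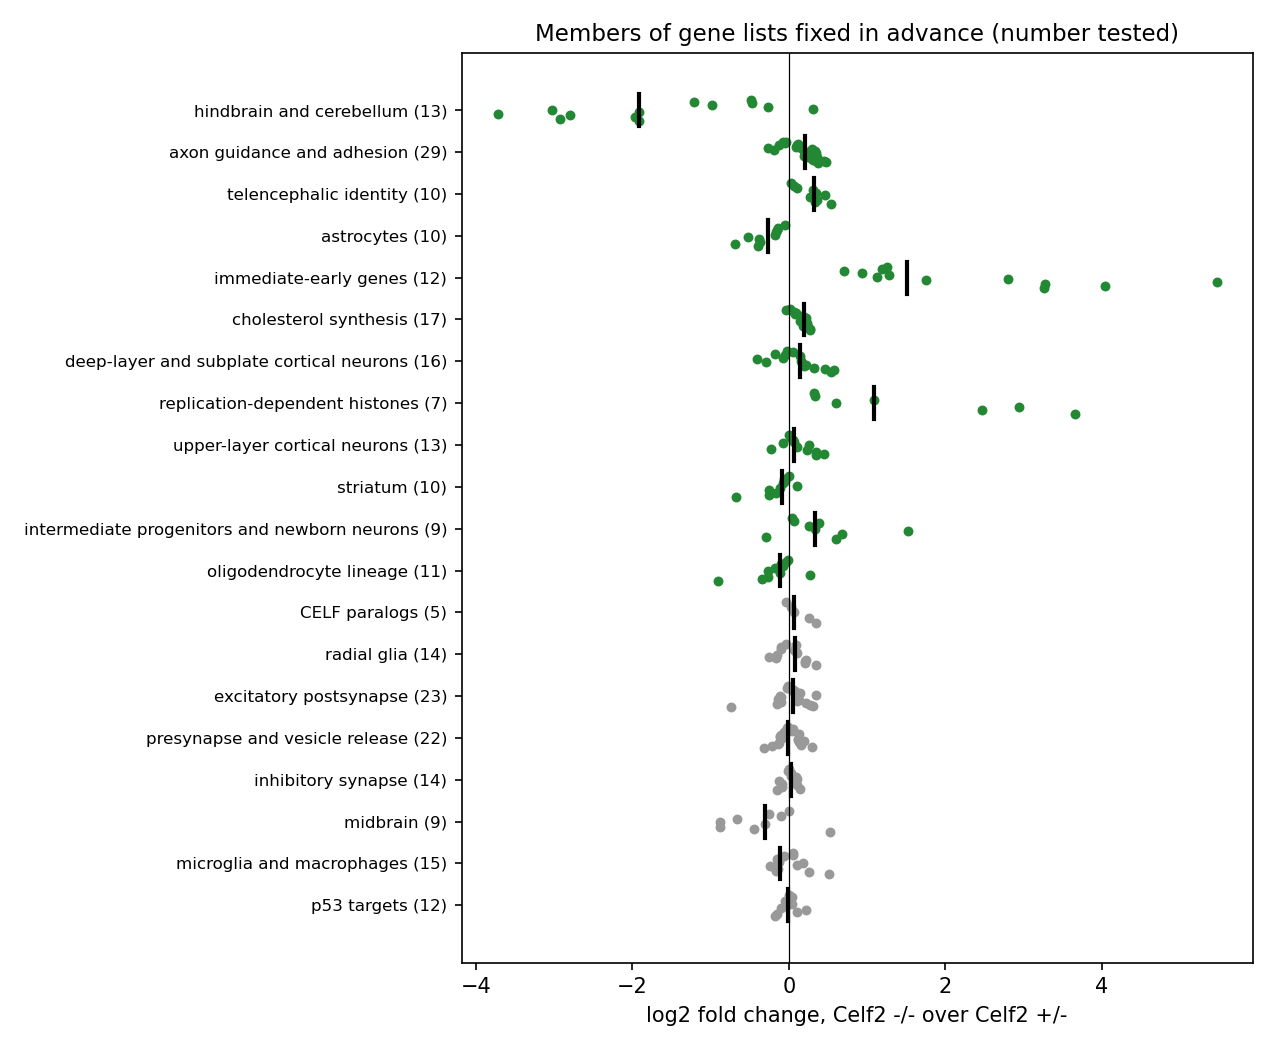
Log2 fold change of each tested member of 20 gene lists, libraries labelled null over heterozygous, with the median of each list as a black bar. Lists with a camera adjusted p below 0.05 at the preset correlation are green and the others grey. The hindbrain and cerebellum list has a median of -1.91 and the telencephalic identity list 0.32, and the upper-layer median of 0.07 turns to -0.03 with library size alone. Under that setting the median over all genes tested was -0.086.

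Immediate-early genes, which neurons transcribe within minutes of stimulation, were higher on average in libraries labelled null, with all 12 members positive and a median of 1.51 (adjusted p = 5.05e-06, and adjusted p = 0.547 with an estimated correlation). No member passed by either adjustment (0 of 12). The median was 0.69 without null replicate 4. Null replicates 2 and 4 lay above every heterozygous library for 12 of 12 genes, whereas null replicate 10 lay at or below the highest heterozygous library for 12 of 12. Fos was at 8.53, 6.43 and 4.50 CPM in heterozygous replicates 6, 7 and 11 and at 78.3, 235 and 4.86 CPM in null replicates 2, 4 and 10. Egr1 was at 17.3, 11.1 and 20.2 CPM and at 126, 323 and 17.6 CPM in the same order. Of 24 replication-dependent histone genes 7 were tested, with a median of 1.09 (adjusted p = 0.00184, and adjusted p = 0.547 with an estimated correlation), and 0 passed by either adjustment. The list deviated from its average by 1.41, 0.83 and -0.90 in null replicates 2, 4 and 10 and by -0.06, -0.22 and -1.47 in heterozygous replicates 6, 7 and 11. Null replicate 2, with 11.8% of counts on Rn45s, also lay at -40.6 on the first principal component, where the others lay between -0.6 and 22.2. Chosen after its values were seen, the structural RNA Rmrp was at 73.2 CPM in that library and at 0.256 to 7.05 CPM in the others. The histone median was 0.56 with an adjusted p of 0.0854 without null replicate 2, and lay at up to 2.17 without null replicate 10. With a CPM minimum the adjusted p was 0.261 although the median was 1.63, and the median was 1.75 without a low-count filter. Structural non-coding RNAs had a median of 0.93 but a camera direction of lower (adjusted p = 0.868).

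**Figure D3:**
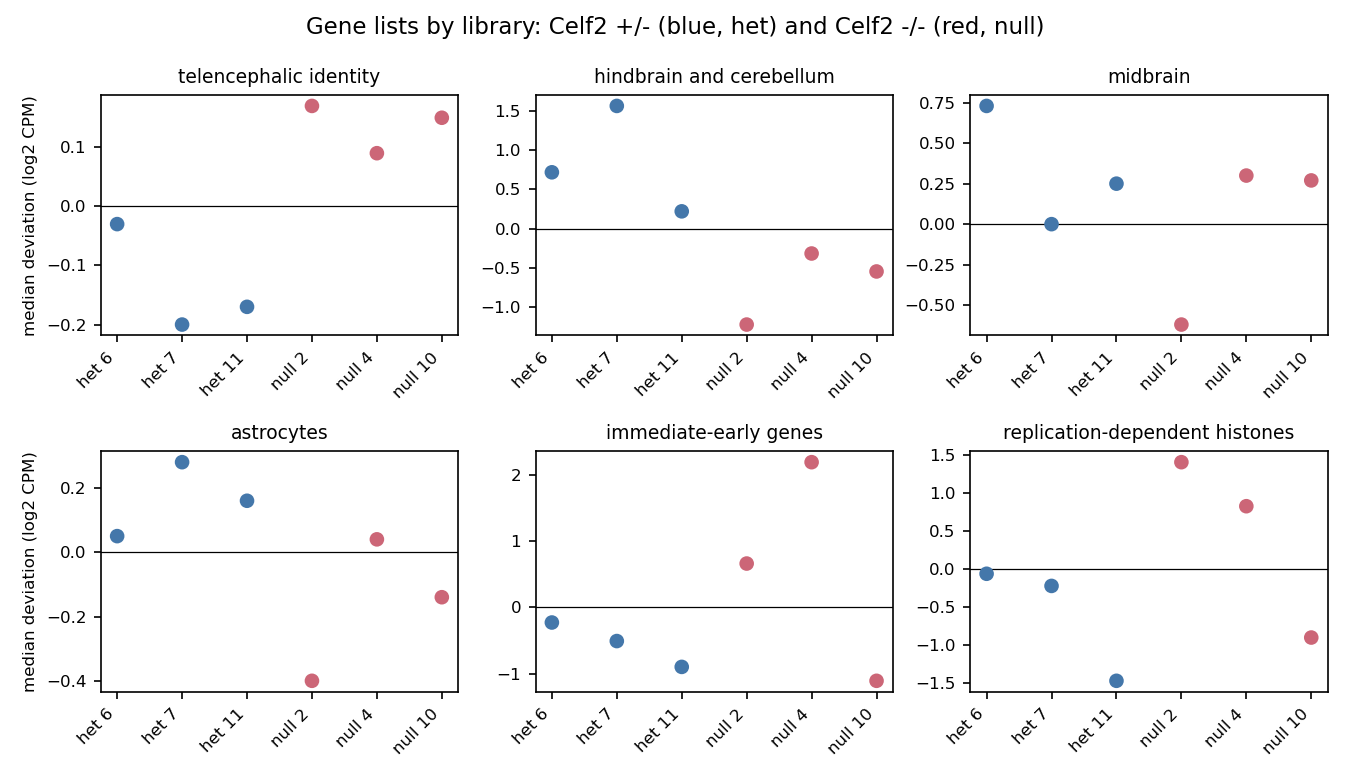
Median deviation of 6 gene lists from each gene's mean log2 CPM over the libraries, for heterozygous replicates (blue) and replicates labelled null (red). Immediate-early genes deviate by 0.66, 2.19 and -1.11 in null replicates 2, 4 and 10, and hindbrain and cerebellum genes by 1.57 in heterozygous replicate 7.

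The synapse lists were not called. Among 23 genes of the excitatory postsynapse 14 were positive and 9 negative (median 0.05, camera adjusted p = 0.907), while fry's test of change in either direction gave an adjusted p of 9.35e-04. Camk2a fell, adjusted over the list alone, and the receptor subunit Grin2b was at 0.31. The presynaptic list had a median of -0.02 (adjusted p = 0.907), with the vesicle protein Syp at -0.32 and Rims1 at 0.30, and the inhibitory synapse list a median of 0.02 (adjusted p = 1). Voltage-gated ion channels had a median of 0.06 (adjusted p = 0.283), with Cacna1b at 0.35. Of these 4 lists, 0 members passed over all genes tested.

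The CELF paralogs had a median of 0.06 (adjusted p = 0.0806), and Celf1 rose, adjusted over the list alone, from 235 ± 25.3 to 299 ± 34.7 CPM (0.35). Over all genes tested the edgeR adjusted p of Celf1 was 0.522, and its values overlapped between the groups. Other neural RNA-binding proteins had a median of 0.06 (adjusted p = 0.359), with Nova1 at -0.23 and Elavl3 at 0.17. Radial glia genes had a median of 0.08 (adjusted p = 0.337), and the matrix protein Tnc (0.34) rose, adjusted over the list alone. Cajal-Retzius genes had a median of -0.18 (adjusted p = 0.907), although Reln, the signal these cells secrete, rose, adjusted over the list alone (0.42). Cell cycle genes had a median of 0.10 (adjusted p = 0.0684), interneuron genes 0.15 (adjusted p = 0.0894), migration genes 0.05 (adjusted p = 0.337) and cytosolic ribosomal proteins 0.01 (adjusted p = 0.938). Integrated stress genes had a median of 0.03 (adjusted p = 0.64), p53 targets -0.01 (adjusted p = 0.868), microglia -0.12 (adjusted p = 0.907) and hypothalamus and pituitary genes -0.16 (adjusted p = 0.283). Interferon genes had a median of 0.01 and a camera direction of lower (adjusted p = 0.998). Medians of the other lists that were not called were 0.16 for hypoxia and glycolysis, 0.15 for choroid plexus and ependyma, 0.08 for glucocorticoid response, 0.02 for endothelium and pericytes, -0.02 for Wnt feedback, -0.07 for meninges, -0.10 for thalamus, -0.49 for the 2 tested erythroid genes and -1.16 for the sex-linked genes. Their camera adjusted p lay between 0.23 and 0.985. In all, 12 of 40 lists were called at the preset correlation, 0 with an estimated correlation and 0 by fry as moving one way, and fry found change in either direction in 5. Adjusted over the list alone, 29 members passed, and 28 lists had 0. That adjustment does not correct across lists, and none of these members passed over all genes tested.

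Genes carrying the GU-rich 11-mer TGTTTGTTTGT in the 3′ UTR, a potential binding element of CELF proteins, were not called as a set. The median log2 fold change of the 618 genes was 0.02 and the camera p was 0.0948 (p = 0.387 with an estimated correlation). In 10000 draws matched on 3′ UTR length and expression the median was 0.027, with 95% of draws between 0.013 and 0.04 (permutation p = 0.355). Genes with at least 3 copies of TGTTTGT gave a camera p of 0.00523, and 0.243 in the permutation matched on length and expression, a test chosen after the first value was seen. The camera p for the 11-mer was 0.047 without heterozygous replicate 7, 0.0476 without heterozygous replicate 11 and 0.0248 without null replicate 2. These camera tests were not matched on 3′ UTR length or expression. In the full data all searched genes without the 11-mer had a median of -0.001, against 0.027 in the matched draws.

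Genes next to Celf2 on chromosome 2 were not called as a set. The 70 tested neighbours had a median log2 fold change of 0.007 and a camera p of 0.873 in the lower direction (p = 0.887 with an estimated correlation). Of them 0 passed over all genes tested. Chosen after their values were seen, the neighbours with the smallest p were Pfkfb3 (0.30, adjusted p = 0.515) and Frmd4a (0.24, adjusted p = 0.527). The direction of the set test was higher without heterozygous replicate 7 (camera p of 0.649) and without null replicate 2 (camera p of 0.713).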

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

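The tests with structural RNAs removed, with the mean Hox level as a covariate, with pups 10 and 11 as a term and with matching of the heptamer genes were chosen after the data were seen. No paired analysis was possible because the pup numbers are not shared between the genotypes. The count of 1 gene became 0 with DESeq2 size factors, a CPM minimum, limma-voom, no robust dispersion, structural RNAs removed and the Hox covariate. It became 2 (2 lower) with upper-quartile factors and with library size alone, 3 (1 higher, 2 lower) without a low-count filter and with the GC and length offset, 11 (0 higher, 11 lower) with the Y-linked covariate, 11 (6 higher, 5 lower) with pups 10 and 11 as a term and 64 (39 higher, 25 lower) with DESeq2. Leaving out single libraries gave 0 to 4 genes, 0 to 3 higher and 0 to 1 lower, the 4 being found without null replicate 10. The 12 lists (8 higher, 4 lower) became 0 (0 and 0) with an estimated correlation and with fry, and numbered 9 to 20 without single libraries, 6 to 14 higher and 2 to 7 lower. The 20 came without heterozygous replicate 6. The other alternatives gave 11 to 16 lists. The Celf2 fold change lay between -0.16 and -0.02 under the other alternatives and between -0.18 and 0.04 without single libraries, where it was 0.03 without heterozygous replicate 6 and 0.04 without null replicate 10. For GU-rich genes the heptamer gave a camera p of 0.00523, and leaving out libraries gave 0.0248 to 0.623, all without matching on 3′ UTR length or expression. For genes near Celf2, leaving out libraries gave 0.528 to 0.881, with the direction turned at 0.649 and 0.713. Among named genes that had not passed, the Hox covariate turned Tpx2 to -0.01, Lef1 to -0.16, Phlda3 to 0.08, Pdk4 to 0.21, Oas1a to 0.04, Alas2 to 0.08, Igf2 to 0.19, Ccdc153 to -0.27 and Pax7 to -0.01, and the Y-linked covariate turned Uba1y to 0.11. Without single libraries, Slc6a13 ranged from -0.42 to 0.06 (turned to 0.01, 0.06 and 0.02 in 3 cases), Igf2 from -0.37 to 0.11 (turned to 0.11 in 1) and Calb2 from -0.36 to 0.00 (turned to 0.00 in 1). With the Hox covariate the hindbrain median was -0.45, in part by construction since Hox genes belong to the list. For every list and gene, this covariate also takes up genotype differences, because the mean Hox level separates the genotypes. Library size alone moved the median over all genes tested from -0.001 to -0.086, and the medians of the 12 called lists moved down with it. Fewer samples enter each fit that leaves out a library, and for the other shifts the cause was not tested. Among the lists not called, the direction of the set test turned, with the adjusted p in brackets, as follows. With the Hox covariate it turned for Cajal-Retzius cells (0.818), excitatory postsynapse (0.708), presynapse and vesicle release (0.0805), p53 targets (0.652), interferon response (0.0191), microglia and macrophages (0.0132) and meninges and fibroblasts (0.0832). Under library size alone it turned for excitatory postsynapse (0.783), inhibitory synapse (0.813), Wnt pathway feedback genes (0.895), interferon response (0.744), microglia and macrophages (0.862), meninges and fibroblasts (0.764) and cytosolic ribosomal proteins (0.7). With the GC and length offset it turned for excitatory postsynapse (0.409), inhibitory synapse (0.601), voltage-gated ion channels (0.547), interferon response (0.9) and microglia and macrophages (0.827). Under upper-quartile factors it turned for inhibitory synapse (0.977), interferon response (0.988), meninges and fibroblasts (0.988) and cytosolic ribosomal proteins (0.991). With a CPM minimum it turned for inhibitory synapse (0.953). Under DESeq2 it turned for inhibitory synapse (0.996) and structural non-coding RNAs (0.945). With limma-voom it turned for inhibitory synapse (0.996), interferon response (0.954) and meninges and fibroblasts (0.867). Under no robust dispersion it turned for inhibitory synapse (0.992). With sex-linked genes removed it turned for inhibitory synapse (0.985). Under the Y-linked covariate it turned for inhibitory synapse (0.853), integrated stress and unfolded protein responses (0.934), structural non-coding RNAs (0.713) and sex-linked (0.853). With no low-count filter it turned for interferon response (0.999) and meninges and fibroblasts (0.999). It also turned without at least 1 single library, with adjusted p over all such fits of 0.0184 to 0.892 for radial glia, 0.335 to 0.941 for Cajal-Retzius cells, 0.702 to 0.992 for excitatory postsynapse, 0.326 to 0.968 for presynapse and vesicle release, 0.748 to 0.992 for inhibitory synapse, 0.267 to 0.991 for Wnt pathway feedback genes, 0.326 to 0.968 for p53 targets, 0.205 to 0.942 for integrated stress and unfolded protein responses, 0.00203 to 0.878 for hypoxia and glycolysis, 0.385 to 0.903 for glucocorticoid response, 0.299 to 0.958 for interferon response, 0.154 to 0.974 for microglia and macrophages, 0.0672 to 0.968 for endothelium and pericytes, 1.24e-08 to 0.837 for meninges and fibroblasts, 0.0253 to 0.881 for cytosolic ribosomal proteins and 0.0237 to 0.994 for structural non-coding RNAs. Of these, the lists that passed in the turned direction were interferon response (0.0191) with the Hox covariate and microglia and macrophages (0.0132) with the Hox covariate. Of the values for 88 named genes other than Celf2, 1692 kept direction and side of the threshold, 34 newly passed it and 11 no longer did. For the 12 called lists 227 kept the direction of the set test and the call and 37 lost the call, and for the 28 others 504 kept the direction without a call and 38 gained one in the same direction. The upper-layer median changed sign, to -0.03, with library size alone while the direction of its set test did not.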

Other observations

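The tests of the Celf2, hindbrain and immediate-early patterns were chosen only after those results were seen, whereas the splits of the samples and the test of developmental stage were written before their results, although part of the criterion of the latter was set aside afterwards. Genes chosen after their values were seen include Nefh and Nefm, neurofilament subunits of large axons. DESeq2 gave Nefh a log2 fold change of -1.05 (adjusted p = 8.06e-04) and Nefm -0.66 (adjusted p = 0.0311), while edgeR's adjusted p was 0.429 for Nefh and 0.581 for Nefm. With the Y-linked covariate, 11 genes passed in edgeR, all lower, among them Hoxa5 (-6.08), Hoxc4 (-5.90), Prph (-2.63) and Sncg (-2.24). The Hoxa5 and Hoxc4 folds rest on heterozygous replicate 7, at 48.5 and 15.7 CPM. Hoxa5 was at 0.672 and 0.228 CPM in heterozygous replicates 6 and 11 and at 0, 0.533 and 0.918 CPM in null replicates 2, 4 and 10, and Hoxc4 was at 1.13 CPM or less in all other libraries. Hoxb3 was at 6.13, 22.3 and 3.45 CPM in heterozygous replicates 6, 7 and 11 and at 1.22, 2.13 and 0.476 CPM in null replicates 2, 4 and 10. The pituitary hormone precursor Pomc was at 3.60, 20.9 and 4.27 CPM in the heterozygous replicates and at 1.46, 2.58 and 1.73 CPM in the null replicates. The erythroid enzyme gene Alas2 had between 146 and 295 counts per library, whereas Hba-a1, Hba-a2, Hbb-b1, Hbb-b2, Hbb-bs and Hbb-bt were listed at 0 counts in all 6 libraries.

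The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The genotype split called 1 gene, and 4 of the 10 splits called as many, with 5 as the highest of the others. That split sets heterozygous replicates 6 and 11 and null replicate 2, the libraries with Ddx3y counts, against the libraries with high Xist, which is a structure of the samples. At an unadjusted p of 0.05 the genotype split counted 1124 genes and the highest other split 2089, and 1788 and 1512 were counted in a further pair of splits, all of which mix the genotypes. These 3 splits set heterozygous replicate 11 and null replicate 10, the most correlated pair, on the same side, which is also a structure of the samples. The remaining split that joins the pair counted 756. For gene lists the genotype split called 12, 4 splits called as many and the highest other split called 18. For GU-rich genes the genotype split gave a camera p of 0.0948, with a p as small in 4 splits and 0.0259 as the smallest of the others. For genes near Celf2 it gave a camera p of 0.873, with a p as small in 9 splits and 0.0816 as the smallest of the others.

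No decrease of Celf2 was called in libraries labelled null, although the interval of 79.9% to 114% of the heterozygous level leaves room for a modest one. A label swap among these libraries, hiding an allele that removes the transcript, would leave at least 1 library with little Celf2, but the lowest library held 72.3% of the highest. That value cannot tell whether any of the libraries came from a null pup, which also stays open. Scaling is also argued against, since the lowest fold change over the scalings was -0.16. An allele that leaves a transcript the gene total cannot tell from the intact one could give the observed level of 95.6%, and it stays open because counts per exon were not analysed here.

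Hindbrain genes were called lower and telencephalic genes higher in libraries labelled null at the preset correlation. With an estimated correlation neither list was called (camera adjusted p = 0.325 and 0.279). Null replicate 2 alone does not account for the lower hindbrain genes, since their median was -1.59 without it. Different amounts of caudal tissue in single hemibrains may contribute and stay open. Mean Hox expression ranged over 3.79 log2 units within the heterozygous group, against a difference of -2.65 between genotypes, but the range rests on heterozygous replicate 7 and was known when the test was chosen. A larger share of cortex as the source would make Camk2a and Nrgn higher, as Neurod6 and Tbr1 were, but both were lower. The higher of their upper 95% bounds (-0.29) does not decide the question, since both genes were picked for being lower. An effect of genotype on brain regions stays open and untested.

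Immediate-early genes were higher in 2 of the 3 libraries labelled null. The median range among the 3 null libraries was 3.57 log2 units, against a median difference of 1.17 between the genotype means. That difference is another measure than the fitted fold change, whose median was 1.51. The comparison restates the pattern and decides nothing. A state of single libraries and a genotype effect that varies between animals both stay open.

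An earlier developmental stage of the null brains was tested with 23 late and 19 early genes, written down without genes already seen as lower. The late genes had a median of -0.17 (camera p = 1.20e-07, and p = 0.107 with an estimated correlation), with 4 of 23 positive. The early genes had a median of 0.08 (p = 0.163, and p = 0.512 with an estimated correlation), with 13 of 19 positive. The criterion written beforehand required both lists to pass and counted a p above 0.05 against the idea, and it was not met. That part of the criterion was set aside after the result was seen, because both medians lay in the predicted direction and a p that misses the threshold excludes nothing. An earlier stage was thus neither supported nor excluded and stays open.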
